A study of Equus caballus with 9 samples.

How the data were processed

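The series measured gene expression in 9 samples of cultured equine cells with Affymetrix expression arrays. Cells were isolated with Ficoll-Paque and grown on plastic for 96 h in medium with 15% fetal bovine serum, non-adherent cells were removed, and 100 ng of total RNA was amplified with an Ovation kit and labelled with biotin. The bone marrow samples are labelled as 3 different horses and the blood samples as 3 others, bled 2 h after electroacupuncture. The adipose samples carry no horse label, and the design text speaks of 3 control horses. Each group was treated as 3 independent replicates. No run or scan dates are given. The repository numbers of the adipose samples do not follow on from those of the other 6, and whether these arrays were processed at another time is not given in the sources used here. The labels abbreviate the blood-derived cells as EA-ADSC.

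The submitters' processing notes name Partek 6.16.0419, Affymetrix Expression Console and Transcriptome Analysis Console 3. The summarization algorithm, the normalization and the genome build are not given in the sources used here. The deposited values are normalized log2 intensities, 1 per probe set and array. They ran from 0.86 to 13.56 with quartiles of 3.35 and 6.02, and the medians of the 9 arrays lay between 4.56 and 4.66. The values were used as deposited, with no further normalization. Detection p-values were not used here and control probe sets could not be told from the annotation, so all 30559 probe sets were tested. The platform annotation names a single gene for 16789 probe sets, several for 343 and none for 13427, which gives 16661 distinct genes. Intensities of different genes are not comparable in absolute terms, and the 3 arrays per group limit the precision.

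A group-means model was fitted to all 9 arrays with lmFit and eBayes of limma 3.58.1 (R 4.3.3), without trend or robust options, which left 6 residual degrees of freedom. The moderated F test compared the 3 groups, and limma's moderated tests of the contrasts compared each pair, two-sided. Benjamini-Hochberg adjustment ran over all probe sets, with a threshold of 0.05 on the adjusted p. Probe sets changed against both control groups were the overlap of the calls of the 2 comparisons that hold the blood-derived cells, set beside 100 simulations of unchanged groups sharing those arrays.

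Gene lists were tested with camera on 1 probe set per gene, the one of the highest mean over all arrays, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. Lists with fewer than 5 measured members got no test. The lists covered MSC surface markers, fibroblast matrix, pan-leukocyte, monocyte and macrophage, osteoclast, T and NK lymphocyte, B lymphocyte, neutrophil, erythroid and platelet, endothelial, pericyte and smooth muscle, adipogenic, thermogenic adipocyte, osteogenic, chondrogenic, HOX paralogs 1 to 8 and 9 to 13, cell cycle, inflammatory cytokines and NF-kB targets, interferon response, MHC class II presentation, MSC trophic and immunomodulatory factors, mobilization and homing, pluripotency, lysosome, hypoxia and glycolysis, immediate early and heat shock, and sex-linked genes. Of their 425 genes 360 were measured. None of the 8 sex-linked genes was among them, so 27 of the 28 lists were tested and the sex of the horses could not be looked at.

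The groups, comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named genes were, for each comparison of the blood-derived cells, the 8 largest rises and 8 largest falls among probe sets naming 1 gene, past the threshold and without overlap between the arrays of the groups, and 5 of each for adipose against bone marrow cells. Where both control groups were concerned, the 5 genes per direction with the largest smaller change were named. For each list and comparison up to 4 members with the smallest adjusted p were available for naming, or, where none passed, up to 2 with the largest moderated statistic, given as values.

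The alternatives were quantile normalization on top of the deposited values, median centring, leaving out dim probe sets (those not above the median of all values in at least 3 arrays), limma-trend, and array weights. Further ones were the replicate number as a block, 1 probe set per gene, the mean of a gene's probe sets, a 2-fold criterion, fits of the 2 groups alone, and leaving out each array. For the lists they also included an estimated correlation, fry and camera on ranks. The labels name different horses for the bone marrow and blood samples, so the replicate numbers do not pair these. Whether adipose samples share horses with another group is not known, since they carry no horse label. Correlations of the residuals of arrays with the same number ran from -0.02 to 0.12, and from 0.01 to 0.12 where 1 was an adipose array. Those of arrays with different numbers ran from -0.12 to 0.04.

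The procedure was tested on simulated data with known changes in 50 probe sets per size. Changes of 1 on the log2 scale were found in only 36%, 48% and 48% of these probe sets in the 3 comparisons. Changes of 2 were found in 70%, 80% and 78%, and changes of 4 in 100%, 100% and 94%, with 6, 10 and 7 false calls. The list test found the shifted list in both comparisons that held it (adjusted p = 2.6e-22 and 3.9e-25) and called 0 other lists in the 3 comparisons at the preset correlation. The simulated genes varied independently of each other. False list calls among genes that vary together were therefore not tested.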

Results

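Gene expression was measured with Affymetrix expression arrays in 9 samples of equine plastic-adherent cells. Bone marrow cells came from 3 untreated horses, adipose cells came from tailhead fat of untreated control horses (3 samples), and blood-derived cells were cultured from the blood mononuclear cells of 3 horses, drawn 2 h after electroacupuncture, in which current is passed between acupuncture needles. The labels describe all 3 groups as mesenchymal cells, and in each the cells left attached after 96 h in medium with 15% fetal bovine serum gave the RNA, of which 100 ng was amplified. The deposited table held 1 log2 intensity for each of 30559 probe sets per array, with values from 0.86 to 13.56 and a median of 4.62. The number of arrays, 3 per group, limits the precision, and the median standard error of a log2 difference between groups was 0.19. Values below are mean log2 intensity ± SD of n = 3 arrays, folds are taken from the log2 differences, and adjusted p-values come from limma. How far dim probe sets lie above background could not be judged, so a fold against a group whose mean lies below the median of 4.62 holds for the deposited values only. Genome coordinates were not used here, and genes are given by symbol and, for the largest changes, by probe set number.

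The 3 groups of arrays had distinct expression profiles. Adipose cells stood apart from the other groups on the first principal component, which held 34.3% of the variance, and blood-derived and bone marrow cells separated on the second, with 20.2%. Whether the adipose arrays were processed at another time is not known. Tissue, treatment and horse changed together between blood-derived and bone marrow cells. Neither separation can therefore be assigned to cell type alone. Pearson correlations across probe sets, which are not independent replicates, were 0.954 to 0.965 between bone marrow and blood-derived arrays, 0.937 to 0.951 between bone marrow and adipose arrays, and 0.936 to 0.950 between blood-derived and adipose arrays. Within groups they were 0.975 to 0.982 for bone marrow, 0.970 to 0.978 for blood and 0.961 to 0.968 for fat. By the moderated F test of limma 2286 probe sets differed among the groups, of which 1725 named a single gene. That count was 1340 without bone marrow replicate 1, 1336 without bone marrow replicate 2, 1514 without blood-derived replicate 2 and 1346 without adipose replicate 3.

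The first comparison sets the cells cultured from blood after electroacupuncture against bone marrow mesenchymal cells cultured in the same way. The blood-derived cells had far higher FGF5, a fibroblast growth factor (8.64 ± 0.37 against 3.86 ± 0.21, 27.5-fold, adjusted p = 3.5e-04), and far lower JAM2, a junctional adhesion molecule (5.19 ± 0.45 against 10.92 ± 0.25, 52.9-fold, adjusted p = 4.1e-05). Cell cycle genes were higher in the blood-derived cells as a list, with a median log2 difference of 1.92. Interferon response genes were lower, by a median of -1.80 with all arrays and -0.61 without bone marrow replicate 3. Both list calls were lost, at an adjusted p = 0.618 with an estimated correlation. Fibroblast matrix genes did not pass the test as a list, with a median of -0.19. At an adjusted p under 0.05, 107 probe sets were higher and 142 lower in the blood-derived cells, naming 94 and 118 genes, and 221 of these 249 changes were at least 2-fold.

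Among the genes higher in the blood-derived cells the largest rise after FGF5 (probe set 15070828) was that of PCSK1, a prohormone convertase (25.6-fold higher, at 8.62 ± 1.19 against 3.94 ± 0.28), and SERPINB2 (15116856), an inhibitor of plasminogen activators, which was 21.7-fold higher at 9.17 ± 0.55 against 4.73 ± 1.15. SLITRK4 (15133650), a neuronal membrane protein, was 16.7-fold higher at 7.11 ± 0.29 against 3.05 ± 0.46. IGFBP3, a carrier of insulin-like growth factors, was at 9.52 ± 1.12 against 5.46 ± 0.14, and the serine protease inhibitor SERPINB10 at 7.72 ± 1.12 against 3.79 ± 0.44. TPBG, a trophoblast glycoprotein, was 14.7-fold higher (adjusted p = 0.00231) and BDKRB1, a bradykinin receptor, 12.9-fold higher (adjusted p = 0.00156). In each of these genes the 3 blood-derived arrays lay above the 3 bone marrow arrays. PCSK1 lost its call without bone marrow replicate 1 (adjusted p = 0.0508), IGFBP3 without bone marrow replicate 1 (0.0539) or 2 (0.0514), and SERPINB10 without the same arrays (0.0539 and 0.0595). SERPINB2 lost it without bone marrow replicate 2 (0.0523) or blood-derived replicate 2 (0.0578) or 3 (0.0535).

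Among the genes lower in the blood-derived cells GMFG (14954018), a regulator of actin branching that is abundant in blood cells, was 33.6-fold lower, at 3.94 ± 0.30 against 9.01 ± 0.28 (adjusted p = 4.1e-05). FAP (15009547), fibroblast activation protein, was 27.3-fold lower at 6.09 ± 0.36 against 10.86 ± 0.31 (adjusted p = 0.0075). The membrane glycoprotein gene GPM6B was 18.3-fold lower (adjusted p = 0.00135) and the growth factor gene IGF2 16.8-fold lower (adjusted p = 0.00156). C1S and C1R, proteases of the classical complement pathway, were at 4.63 ± 0.37 against 9.85 ± 0.95 and at 4.74 ± 0.72 against 9.54 ± 1.01, and CDO1, a cysteine dioxygenase, was at 5.78 ± 1.38 against 10.03 ± 0.58. C1S and C1R lost their calls without any 1 of the 6 arrays of these groups, with adjusted p from 0.0558 to 0.0765 and from 0.0535 to 0.0889. Their log2 differences in these fits, which have fewer arrays, ran from -4.68 to -5.57 and from -4.21 to -5.15. CDO1 lost its call without bone marrow replicate 1 (0.0663), 2 (0.109) or 3 (0.0865) and without blood-derived replicate 3 (0.0587), and with the replicate number as a block (0.0528).

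Of the 24 measured cell cycle genes 5 were higher in the blood-derived cells over all probe sets, and adjusted over the list alone 23 were. The list had an adjusted p of 3.5e-21 by camera with a preset correlation and an adjusted p = 0.618 with an estimated correlation, and fry gave an adjusted p of 0.076. CDK1, the mitotic kinase, was 8.84-fold higher (9.54 ± 0.50 against 6.39 ± 0.33, adjusted p = 0.0117), and CCNB2, a mitotic cyclin, was 6.78-fold higher (8.56 ± 0.35 against 5.80 ± 0.25, adjusted p = 0.0303). AURKA, a mitotic kinase, and MCM6, of the replicative helicase, were 3.24-fold and 3.41-fold higher. CDK1 lost its own call without bone marrow replicate 1 (adjusted p = 0.0625), and CCNB2, AURKA and MCM6 lost theirs without any 1 of the 6 arrays compared, with adjusted p from 0.0697 to 0.114, from 0.0535 to 0.126 and from 0.0562 to 0.151. In those 6 fits the log2 differences of CCNB2, AURKA and MCM6 ran from 2.56 to 2.89, from 1.49 to 1.83 and from 1.55 to 1.95. CCNB2 and MCM6 also lost it without adipose replicate 3 (0.059 and 0.0703), and MCM6 after median centring of the arrays (0.0541).

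Interferon response genes were lower in the blood-derived cells as a list, with a median log2 difference of -1.80 over 17 members, each of them below 0. The list had an adjusted p of 2.1e-06 by camera with a preset correlation and an adjusted p = 0.618 with an estimated correlation, and fry gave 0.236. None of the members passed limma's threshold over all probe sets or adjusted over the list alone, and 8 had an unadjusted p under 0.05. OAS1, an antiviral oligoadenylate synthetase, was at 6.05 ± 0.38 against 8.04 ± 1.35 (adjusted p = 0.187), and IFI44 at 4.44 ± 0.52 against 7.50 ± 2.18 (adjusted p = 0.199). Bone marrow replicate 3 held the highest value of 15 of the 17 members, and without it the median was -0.61, with the list still called at the preset correlation (adjusted p = 2.1e-07). The same array held the highest value of 8 of 15 T and NK lymphocyte markers.

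Monocyte and macrophage markers were lower as a list (median -0.31, adjusted p = 0.00111, or adjusted p = 0.618 with an estimated correlation and 0.144 by fry). Of the 18 members 1 was lower over all probe sets and 2 adjusted over the list alone. FCER1G, an Fc receptor subunit of myeloid cells, was at 3.93 ± 0.49 against 7.53 ± 1.09 (adjusted p = 0.0206). Bone marrow replicate 1 held the highest value of 9 of the 18 markers, and without it the median was -0.13. FCER1G lost its call without bone marrow replicate 3 (0.0684) or blood-derived replicate 2 (0.0833) or 3 (0.0768). The pan-leukocyte list was lower as well (median -0.51, adjusted p = 0.00911, or adjusted p = 0.618 with an estimated correlation). This list's call was also lost by fry (0.144), without bone marrow replicate 1 (median -0.31, adjusted p = 0.059) and with dim probe sets left out (0.1). Over all probe sets 1 of its 13 members was higher, a call lost in 7 of the 9 fits without 1 array, and none lower, and adjusted over the list alone 1 was higher and 2 lower. HOX genes of paralog groups 1 to 8, which encode body-axis position, were lower as a list (median -0.33, adjusted p = 2.0e-04, or adjusted p = 0.264 with an estimated correlation and 0.011 by fry). Over all probe sets 1 of 16 members was lower, and adjusted over the list alone 4 were. HOXC6 was 7.84-fold lower, at 4.25 ± 0.53 against 7.22 ± 0.19 (adjusted p = 0.00336).

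Among MSC surface markers 2 of 13 members rose over all probe sets, and adjusted over the list alone 4 were higher and 2 lower, with a list adjusted p of 0.271. ALCAM, an adhesion molecule used as an MSC marker, was 7.86-fold higher (9.42 ± 0.40 against 6.44 ± 0.32, adjusted p = 0.00336), and CD44, the hyaluronan receptor, 1.87-fold higher (adjusted p = 0.0282, and 0.0562 to 0.121 without any 1 of the 6 arrays compared). The log2 difference of CD44 ran from 0.81 to 0.96 in those fits. Of 20 fibroblast matrix members 1, FAP, was lower over all probe sets, and adjusted over the list alone 2 were higher and 2 lower (list adjusted p = 0.441). The intermediate filament gene DES, of the pericyte and smooth muscle list, was 12.6-fold higher (9.03 ± 0.86 against 5.38 ± 0.31, adjusted p = 0.0048) as 1 of 11 members, the same number as adjusted over the list alone. By both counts, over all probe sets and adjusted over the list alone, the chondrogenic list had 1 of 11 members lower. This was COL11A1, a fibrillar collagen, at 5.97 ± 0.16 against 7.50 ± 0.28 (adjusted p = 0.011). In the hypoxia and glycolysis list 1 of 14 members was higher, CA9, a hypoxia-induced carbonic anhydrase (9.96 ± 0.57 against 8.06 ± 0.13, adjusted p = 0.0244), and adjusted over the list alone 3 were higher and 2 lower. CA9 lost its call without bone marrow replicate 1 (0.103), 2 (0.11) or 3 (0.0747) or blood-derived replicate 2 (0.094). The mobilization and homing list had 1 of 14 members lower, KITLG, the ligand of the KIT receptor (adjusted p = 0.0282), and 3 lower adjusted over the list alone. KITLG lost its call without bone marrow replicate 1 (0.111), 2 (0.0878) or 3 (0.0933), blood-derived replicate 1 (0.0652) or adipose replicate 3 (0.0545), and with the replicate block (0.0596). The osteoclast list had 1 of 12 members lower, ATP6V0D2, a proton pump subunit (adjusted p = 0.0385), and 2 adjusted over the list alone, and that gene kept its call only without blood-derived replicate 1, the other adjusted p running from 0.0514 to 0.151.

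The remaining lists had no member past limma's threshold over all probe sets. Adjusted over the list alone, 2 of 16 MSC trophic and immunomodulatory factors were higher and 1 lower, 1 of 15 lysosome genes was lower and 1 of 8 MHC class II presentation genes was lower. At an unadjusted p under 0.05 these lists had 9, 3 and 3 members. No member passed either count among T and NK lymphocyte (0 of 15 at an unadjusted p under 0.05), B lymphocyte (0 of 10), neutrophil (1 of 9), erythroid and platelet (0 of 10), and endothelial markers (1 of 11). The same held for adipogenic (3 of 10), thermogenic adipocyte (1 of 9), osteogenic (5 of 11), HOX paralog 9 to 13 (3 of 15), inflammatory cytokine and NF-kB target (1 of 14), pluripotency (2 of 11) and immediate early and heat shock genes (5 of 13). FGF2, a fibroblast growth factor, was at 8.18 ± 0.08 against 7.17 ± 0.30 (adjusted p = 0.064), and passed without adipose replicate 2 (0.0443) and with dim probe sets left out (0.0348). IGF1 was at 4.48 ± 0.10 against 5.92 ± 0.60 (adjusted p = 0.0755), and passed with dim probe sets left out (0.0421) and with the replicate number as a block (0.0403). The pluripotency factor POU5F1 was at 5.63 ± 0.17 against 6.10 ± 0.17 (adjusted p = 0.239) and MYC at 8.27 ± 0.35 against 7.57 ± 0.24 (adjusted p = 0.212). Without bone marrow replicate 3 camera also called the osteoclast (adjusted p = 0.027), HOX paralog 9 to 13 (0.0413), MHC class II (0.0316), lysosome (0.0413) and immediate early lists (6.9e-05). It called MHC class II without bone marrow replicate 2 (0.0124) and immediate early genes without blood-derived replicate 2 (0.0122) and with the replicate block (0.0275). The lysosome list was called without adipose replicate 1 (0.0435) or 2 (0.0251), and mobilization and homing without adipose replicate 2 (0.0299).

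With all arrays camera called 5 of 27 lists at a preset correlation and 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05, and the rotation test fry called 1. Of the 33 named genes with a call in this comparison, 14 kept it in all 9 fits that left out 1 array. The 249 calls became 86 without bone marrow replicate 1, 87 without bone marrow replicate 2, 136 without bone marrow replicate 3, 125 without blood-derived replicate 2, 129 without blood-derived replicate 3 and 384 without adipose replicate 2. Tissue, treatment and horse changed together between these groups, so none of the differences can be assigned to electroacupuncture alone.

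**Figure D1:**
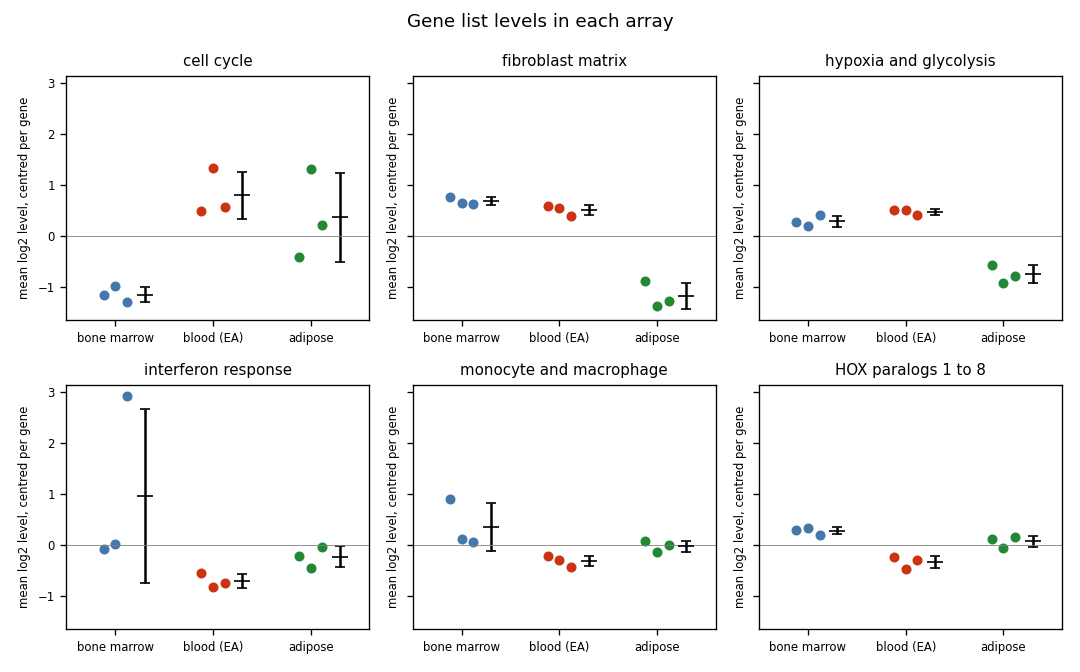
Mean level of 6 gene lists in each of the 9 arrays (points, log2 intensity centred on each gene's mean over all arrays) by group, with bars for the group mean ± SD of 3 arrays. The cell cycle list lies at -1.16 ± 0.15 in bone marrow cells against 0.79 ± 0.46 in blood-derived cells, and the fibroblast matrix list at -1.19 ± 0.26 in adipose cells.

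The second comparison sets the same blood-derived cells against adipose mesenchymal cells of untreated horses. In the blood-derived cells TGFBI, a matrix protein induced by TGF-beta, was 83.2-fold higher (10.99 ± 0.29 against 4.61 ± 0.38, adjusted p = 1.3e-05). ACTG2, a smooth muscle actin, was 72.2-fold higher (12.50 ± 0.16 against 6.33 ± 1.04, adjusted p = 2.0e-04). The adipose cells had far higher MMP3, stromelysin (12.34 ± 0.10 against 3.86 ± 0.68, 358.7-fold, adjusted p = 1.3e-05), and PTX3, a secreted pentraxin (11.68 ± 0.26 against 3.88 ± 1.30, 223.0-fold, adjusted p = 2.8e-04). Fibroblast matrix and hypoxia and glycolysis genes were higher in the blood-derived cells as lists at the preset correlation, and each had an adjusted p = 0.0807 with an estimated correlation. At the threshold, 1067 probe sets were higher and 1049 lower in the blood-derived cells, naming 834 and 696 genes, and 1192 of the changes were at least 2-fold.

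TNC, tenascin C, was 56.0-fold higher in the blood-derived cells (adjusted p = 1.0e-04), EDN1, the precursor of endothelin-1, 43.3-fold higher (adjusted p = 3.0e-04), and CTHRC1, a secreted collagen repeat protein, 36.3-fold higher (adjusted p = 1.5e-04). ANKRD1, an ankyrin repeat protein of muscle, was at 10.56 ± 2.08 against 4.56 ± 0.46 (adjusted p = 0.00612). CFAP299 was 59.5-fold higher, next to FGF5, which was 37.5-fold higher. ALDH1A1, a retinaldehyde dehydrogenase, was at 10.04 ± 1.27 in adipose against 3.78 ± 0.52 in blood-derived cells, and AGTR1, the angiotensin II receptor, at 8.98 ± 0.76 against 2.88 ± 0.60. VEGFD, a lymphatic growth factor, was at 10.20 ± 0.70 in adipose cells (adjusted p = 1.1e-04). GMFG was 44.5-fold higher there (9.41 ± 0.20 against 3.94 ± 0.30), and the integrin-like gene ITGBL1 56.5-fold higher. FABP4, the adipocyte fatty acid binding protein, was at 8.56 ± 2.54 in adipose cells against 2.98 ± 0.16 (adjusted p = 0.0171), a call that was lost without blood-derived replicate 1 (0.0534), 2 (0.0584) or 3 (0.0527). In each of these genes the arrays of the 2 groups did not overlap.

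In the blood-derived cells relative to adipose cells the fibroblast matrix list had 10 of 20 members higher and 1 lower over all probe sets, 15 higher and 1 lower adjusted over the list alone, and a median of 1.81. The list had an adjusted p of 2.2e-10 by camera with a preset correlation and an adjusted p = 0.0807 with an estimated correlation. FN1, fibronectin, was 16.8-fold higher (10.25 ± 0.50 against 6.17 ± 0.29), SPARC, a matrix glycoprotein, 9.98-fold higher (12.15 ± 0.02 against 8.83 ± 0.57), and COL3A1, a fibrillar collagen, 6.47-fold higher (9.11 ± 0.26 against 6.42 ± 0.37). Of the hypoxia and glycolysis genes 10 of 14 were higher and 1 lower over all probe sets and 12 higher and 1 lower adjusted over the list alone, with a median of 1.21. This list had an adjusted p of 3.1e-10 at the preset correlation and an adjusted p = 0.0807 with an estimated correlation. BNIP3, a hypoxia-induced mitophagy receptor, was 7.25-fold higher (11.68 ± 0.36 against 8.82 ± 0.08), CA9 16.3-fold higher (9.96 ± 0.57 against 5.94 ± 0.34), and the glycolytic genes PGK1 and ALDOA 2.69-fold and 2.20-fold higher.

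Of 11 pericyte and smooth muscle genes 4 were higher over all probe sets and 5 adjusted over the list alone. TAGLN, transgelin, was 27.8-fold higher (11.42 ± 0.20 against 6.63 ± 1.03, adjusted p = 6.3e-04), DES 17.7-fold higher and CNN1, calponin, 8.78-fold higher. ACTA2, a smooth muscle actin, was at 12.84 ± 0.11 against 9.49 ± 1.62 (adjusted p = 0.0194), a call lost without blood-derived replicate 1 (0.0609), 2 (0.0584) or 3 (0.0613). The list's median was 0.31, with an adjusted p of 0.0163 by camera, 0.113 by camera on ranks, and adjusted p = 0.419 with an estimated correlation. The median was 0.48 without blood-derived replicate 2 and 0.18 without adipose replicate 3. HOX genes of paralog groups 9 to 13 were lower as a list (median -0.31, adjusted p = 0.0444, or adjusted p = 0.532 with an estimated correlation). The call was lost without blood-derived replicate 2 (0.139), adipose replicate 2 (0.0658) or adipose replicate 3 (0.0794). It was also lost with dim probe sets left out (0.151) and by fry (0.0776). Over all probe sets 1 of its 15 members was higher, HOXB9 (1.63-fold, adjusted p = 0.0179), and 1 lower, HOXC10 (1.89-fold, adjusted p = 0.0301), and adjusted over the list alone 1 was higher and 2 lower. HOXB9 lost its call without blood-derived replicate 3 (0.055) or adipose replicate 3 (0.0548), and HOXC10 without bone marrow replicate 1 (0.0548), 2 (0.0551) or 3 (0.0511) or blood-derived replicate 2 (0.0961) or 3 (0.0837).

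Several lists that camera did not call as a whole held members that changed, and fry called some of these lists. Of 13 MSC surface markers 4 were higher and 1 lower by both counts, among them the integrin ITGB1 (2.92-fold, adjusted p = 0.0013), ALCAM (5.14-fold, adjusted p = 0.00265) and ENG, endoglin (1.91-fold, adjusted p = 0.00374). PDGFRA, a growth factor receptor, was lower, at 5.66 ± 1.09 against 8.15 ± 0.17 (adjusted p = 0.0143, and 0.0521 without adipose replicate 3). Of 16 trophic and immunomodulatory factors 4 were higher over all probe sets and 6 adjusted over the list alone, among them TGFB1 (3.42-fold, adjusted p = 0.00705), VEGFA (3.78-fold, adjusted p = 0.0111) and FGF2 (2.23-fold, adjusted p = 0.0119). The fourth, HGF (adjusted p = 0.0224), lost its call without blood-derived replicate 2 or 3 or any 1 adipose array (0.0542 to 0.0744). That list had an adjusted p of 0.0665, and of 0.0397, 0.0414 and 0.0331 without blood-derived replicate 1 or 3 or adipose replicate 1. Adipogenic genes had 3 of 10 members lower in the blood-derived cells by both counts, FABP4, CIDEC and PPARG, all concerned with fat storage. CIDEC lost its call without blood-derived replicate 1 (0.0622), 2 (0.067) or 3 (0.0578) or adipose replicate 3 (0.0608), and PPARG without blood-derived replicate 1 (0.0624), 2 (0.0799) or 3 (0.065) or adipose replicate 2 (0.0624) or 3 (0.0815) and with the replicate block (0.0535). The osteogenic list had 2 of 11 members higher and 3 adjusted over the list alone, with DLX5, a bone transcription factor, 13.7-fold higher (adjusted p = 0.00142). The other, PHEX (adjusted p = 0.0401), lost its call without any 1 array but blood-derived replicate 1 (0.0509 to 0.113) and with the replicate block (0.0646). The chondrogenic list had 1 of 11 higher by both counts, COL11A1 (2.71-fold). HOXC6 was 5.73-fold lower (adjusted p = 0.00193) as 1 of 16 members of paralog groups 1 to 8, of which 3 were lower adjusted over the list alone. The pan-leukocyte list had 1 of 13 members higher by both counts. In the thermogenic adipocyte list EBF2, a transcription factor of brown adipocyte precursors, was 2.75-fold lower (adjusted p = 0.002).

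Further single members passed. The thermogenic list of 9 also had 1 member higher over all probe sets, the deiodinase DIO2 (adjusted p = 0.0362), and 1 higher and 2 lower adjusted over the list alone. DIO2 lost its call without any 1 array but adipose replicate 3 (0.0519 to 0.0973) and with the replicate block (0.0811). The 18 monocyte and macrophage markers had 1 member lower over all probe sets and 2 adjusted over the list alone, with FCER1G 6.27-fold lower (adjusted p = 0.0193). FCER1G lost its call without blood-derived replicate 2 or 3 or adipose replicate 1 or 3 (0.0535 to 0.068). Among 15 lysosome genes 1 was higher, the protease CTSB (1.91-fold, adjusted p = 0.0222), and 1 lower, the cholesterol transporter NPC1 (2.65-fold, adjusted p = 0.0158), with 1 higher and 2 lower adjusted over the list alone. CTSB lost its call without blood-derived replicate 2 (0.0752) or 3 (0.0694) or adipose replicate 3 (0.0596) and with the replicate block (0.057), and NPC1 without blood-derived replicate 1 (0.0536). By both counts 1 member was lower among 12 osteoclast genes, the protease CTSK (3.72-fold, adjusted p = 0.0311), among 17 interferon response genes, USP18 (adjusted p = 0.0366), and among 8 MHC class II genes, CTSS (adjusted p = 0.0195). Of 15 T and NK lymphocyte markers 1, NKG7, was higher by both counts (4.21-fold, adjusted p = 0.0468). CTSK lost its call without bone marrow replicate 1 or 2, blood-derived replicate 1 or 2 or adipose replicate 1 or 3 (0.0549 to 0.101), and USP18 without any 1 blood-derived array or adipose replicate 1 or 3 (0.0907 to 0.115). CTSS lost it without blood-derived replicate 1 or 3 or adipose replicate 1 or 3 (0.0555 to 0.0681), and NKG7 without any 1 array but bone marrow replicate 3 (0.0505 to 0.137). With the replicate block CTSK was at 0.0666 and NKG7 at 0.0779.

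No member passed limma's threshold over all probe sets or adjusted over the list alone among cell cycle genes (4 of 24 at an unadjusted p under 0.05), B lymphocyte (2 of 10), neutrophil (2 of 9), erythroid and platelet (0 of 10), and endothelial markers (2 of 11). The same held for inflammatory cytokine and NF-kB target (4 of 14), mobilization and homing (3 of 14), pluripotency (1 of 11) and immediate early and heat shock genes (1 of 13). The cell cycle list had a median of 0.44 and an adjusted p of 0.0844, which was 0.0233 without blood-derived replicate 1, 0.0414 without blood-derived replicate 3 and 7.2e-07 without adipose replicate 2, the adipose array with the highest cell cycle level. It was 0.0161 with the replicate block and 0.0298 by camera on ranks, and replicate 2 had the highest cell cycle level in each of the 3 groups. Blood-derived replicate 2 was at a list level of 1.32 against 0.49 and 0.57 in replicates 1 and 3, so the difference is smaller without it. HOX paralogs 1 to 8, also at 0.0844, were at 0.0348 and 0.0435 without blood-derived replicates 1 and 3. The integrin ITGA4 was at 7.85 ± 0.83 in blood-derived against 5.37 ± 1.59 in adipose cells (adjusted p = 0.0848, and 0.00601 without adipose replicate 2).

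With all arrays camera called 4 of 27 lists at a preset correlation and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05, and fry called 9. By fry, fibroblast matrix (adjusted p = 6.6e-05), hypoxia and glycolysis (3.3e-05), pericyte and smooth muscle (0.00593) and MSC surface markers (0.00805) were higher. So were trophic factors (0.013), osteogenic (0.0176) and endothelial genes (0.0186), while adipogenic genes and HOX paralogs 1 to 8 were lower (0.0176 each). Of the 60 named genes with a call in this comparison 41 kept it in all 9 fits that left out 1 array, and the 2116 calls became 1176 without blood-derived replicate 2, 1294 without blood-derived replicate 3 and 1341 without adipose replicate 3. Tissue and treatment changed together here too. Whether horse changed as well is not known, since the adipose samples carry no horse label. The repository numbers of the adipose samples do not follow on from those of the other 6, and a possible difference in processing date cannot be told apart from tissue.

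**Figure D2:**
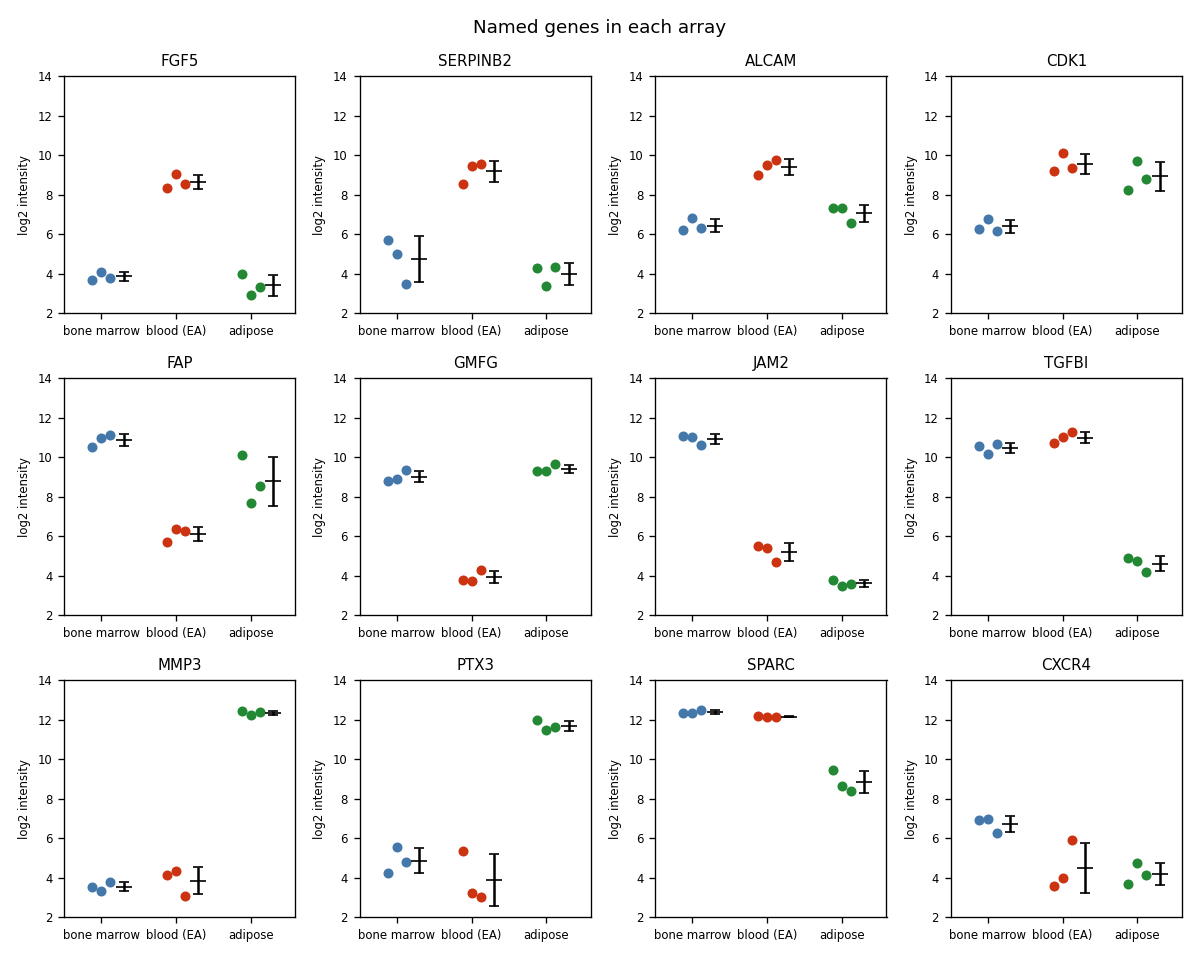
Log2 intensity of 12 named genes in each of the 9 arrays (points) by group, with bars for the group mean ± SD of 3 arrays. FGF5 lies at 8.64 ± 0.37 in blood-derived cells against 3.86 ± 0.21 in bone marrow and 3.42 ± 0.53 in adipose cells, and MMP3 at 12.34 ± 0.10 in adipose cells.

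The comparison of the untreated groups gives the difference between adipose and bone marrow cells without electroacupuncture. Adipose cells again had far higher MMP3 (444.9-fold against bone marrow, adjusted p = 1.3e-05) and PTX3 (112.9-fold, adjusted p = 5.8e-04). They had far lower JAM2 (3.62 ± 0.17 against 10.92 ± 0.25, 157.2-fold, adjusted p = 1.3e-05) and TGFBI (4.61 ± 0.38 against 10.47 ± 0.26, 58.2-fold, adjusted p = 1.9e-05). In adipose cells VEGFD was at 10.20 ± 0.70 against 3.80 ± 0.30 (adjusted p = 8.6e-05), AGTR1 at 8.98 ± 0.76 against 2.80 ± 0.12 (adjusted p = 1.9e-04) and ALDH1A1 at 10.04 ± 1.27 against 4.55 ± 1.15 (adjusted p = 0.00389). SFRP2, a secreted Wnt antagonist, was 61.1-fold lower, SYTL2, a Rab27 effector, 50.9-fold lower, and ACTG2 43.1-fold lower. At the threshold, 865 probe sets were higher and 992 lower in adipose cells, naming 578 and 794 genes, and 1037 of the changes were at least 2-fold.

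In adipose relative to bone marrow cells the fibroblast matrix list had 12 of 20 members lower over all probe sets, 14 adjusted over the list alone and a median of -2.15. The list had an adjusted p of 1.7e-13 by camera with a preset correlation and an adjusted p = 0.0512 with an estimated correlation. SPARC was 11.8-fold lower (8.83 ± 0.57 against 12.39 ± 0.09), TNC 22.8-fold lower (3.67 ± 0.63 against 8.18 ± 0.26) and BGN, biglycan, 4.48-fold lower (8.68 ± 0.16 against 10.84 ± 0.21). Of the hypoxia and glycolysis genes 9 of 14 were lower over all probe sets and, adjusted over the list alone, 11 lower and 1 higher, with a median of -1.14. This list had an adjusted p of 1.1e-09 at the preset correlation and an adjusted p = 0.0512 with an estimated correlation. BNIP3 was 5.58-fold lower, PGK1 2.42-fold, ALDOA 2.26-fold and LDHA, lactate dehydrogenase, 1.80-fold.

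Of 24 cell cycle genes 8 were higher in adipose than in bone marrow cells over all probe sets and 16 adjusted over the list alone, with a median of 1.65 that was 1.08 without adipose replicate 2. The list had an adjusted p of 1.1e-09 by camera with a preset correlation and an adjusted p = 0.432 with an estimated correlation. AURKA was 4.04-fold higher (8.24 ± 0.50 against 6.22 ± 0.15, adjusted p = 0.00442), CDK1 5.77-fold (8.92 ± 0.75 against 6.39 ± 0.33, adjusted p = 0.00843) and CCNB2 5.97-fold (8.38 ± 0.97 against 5.80 ± 0.25, adjusted p = 0.0119). BUB1B (adjusted p = 0.0138) lost its call without bone marrow replicate 1 or 3 (0.0543 in each). Interferon response genes had a median of -1.24 and an adjusted p of 0.0245, or an adjusted p = 0.697 with an estimated correlation. That call was lost without bone marrow replicate 3 (median -0.16, adjusted p = 0.153), adipose replicate 1 (0.0574) or adipose replicate 2 (0.0793). It was also lost with dim probe sets left out (0.11) and by fry (0.31). No member of 17 passed limma's threshold by either count, with 5 at an unadjusted p under 0.05.

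Smaller lists were lower in adipose cells. Pericyte and smooth muscle genes had 4 of 11 members lower by both counts, among them TAGLN (31.9-fold, 6.63 ± 1.03 against 11.62 ± 0.13) and CNN1 (11.5-fold, 5.55 ± 0.53 against 9.08 ± 0.58). The other 2 lost their calls, ACTA2 (adjusted p = 0.0172) without any 1 bone marrow array (0.0598 to 0.0624), and LMOD1 (adjusted p = 0.0329) without any 1 array but bone marrow replicate 2 and adipose replicate 2 (0.0512 to 0.112) and with the replicate block (0.0675). The list had a median of -0.50 and an adjusted p of 0.0336, or adjusted p = 0.39 with an estimated correlation. Without bone marrow replicate 3 or adipose replicate 2 that list's adjusted p was 0.0516 or 0.0674, and by camera on ranks 0.126. Osteogenic genes had 2 of 11 members lower over all probe sets and 3 adjusted over the list alone, with DLX5 10.6-fold lower (adjusted p = 0.0025), a median of -0.31 and an adjusted p of 0.0336, or adjusted p = 0.334 with an estimated correlation. The other member, SPP1 (adjusted p = 0.0423), lost its call without any 1 array but bone marrow replicate 3 (0.0596 to 0.136) and with the replicate block (0.0644). The osteogenic call was lost without adipose replicate 1 (0.06), 2 (0.0674) or 3 (0.0698) and with dim probe sets left out (0.0608). The pan-leukocyte list had 2 of 13 members lower over all probe sets and 3 adjusted over the list alone, with a median of -0.68 and an adjusted p of 0.0119, or adjusted p = 0.39 with an estimated correlation. CORO1A, an actin regulator of leukocytes, was 1.74-fold lower (adjusted p = 0.0333) and RAC2, a leukocyte GTPase, 2.15-fold lower (adjusted p = 0.0398). CORO1A lost its call without bone marrow replicate 1 or 3, blood-derived replicate 2 or 3 or adipose replicate 2 or 3 (0.0548 to 0.107), and RAC2 without any 1 array but bone marrow replicate 2 (0.0563 to 0.0966).

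Of 14 mobilization and homing genes 4 were lower over all probe sets, and adjusted over the list alone 4 were lower and 1 higher. KITLG was 5.46-fold lower (adjusted p = 0.00382), ITGA4 21.1-fold (5.37 ± 1.59 against 9.77 ± 0.24, adjusted p = 0.0112) and the chemokine receptor ACKR3 8.20-fold (adjusted p = 0.0127). CXCR4 (adjusted p = 0.0405) lost its call without any 1 bone marrow or adipose array or blood-derived replicate 2 (0.0545 to 0.128) and with the replicate block (0.0677). VEGFA was 7.03-fold lower (adjusted p = 0.00225) and HGF, hepatocyte growth factor, 7.60-fold lower (adjusted p = 0.00429), among 3 of 16 trophic factors over all probe sets and 5 adjusted over the list alone. The third, IGF1 (adjusted p = 0.0196), lost its call without bone marrow replicate 2 (0.0617) or adipose replicate 3 (0.0652). Of 13 MSC surface markers 1 was higher and 3 lower over all probe sets and 2 higher and 4 lower adjusted over the list alone, with ENG 1.74-fold lower (adjusted p = 0.00801) and ITGB1 2.05-fold lower (adjusted p = 0.00856). CD44, the higher member (adjusted p = 0.0178), lost its call without bone marrow replicate 1 or 2 or adipose replicate 3 (0.0571 to 0.0737), and NT5E, lower (adjusted p = 0.0425), without any 1 array but blood-derived replicates 2 and 3 (0.0526 to 0.134) and with the replicate block (0.0686). By both counts the chondrogenic list had 1 of 11 members lower, COL11A1 (7.87-fold, adjusted p = 1.7e-04), and the monocyte and macrophage list 1 of 18 lower, the adaptor TYROBP (5.58-fold, adjusted p = 0.0132). The adipogenic list had 1 of 10 higher, CIDEC (5.39-fold, adjusted p = 0.0214). CIDEC lost that call without bone marrow replicate 1 (0.0761), 2 (0.051) or 3 (0.0764) or adipose replicate 3 (0.0643). In the thermogenic adipocyte list of 9, EBF2 was 2.95-fold higher (adjusted p = 0.00149) and DIO2 3.13-fold lower (adjusted p = 0.00455), with 2 higher and 1 lower adjusted over the list alone.

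Of 12 osteoclast genes 1 was lower by both counts, ATP6V0D2 (5.99-fold, adjusted p = 0.0177, and 0.0697, 0.0662, 0.0505 and 0.0509 without bone marrow replicate 1 or 3 or adipose replicate 2 or 3). Of 8 MHC class II genes 1 was lower over all probe sets, CD86, a T cell costimulator (adjusted p = 0.029), and 3 adjusted over the list alone. CD86 lost its call without bone marrow replicate 1 or 3, blood-derived replicate 2 or any 1 adipose array (0.0505 to 0.0828) and with the replicate block (0.0613). Of 15 lysosome genes 2 were lower, CTSB (adjusted p = 0.0448) and the hexosaminidase HEXA (adjusted p = 0.0483), with 2 higher and 2 lower adjusted over the list alone. Both lost their calls without any 1 bone marrow array, blood-derived replicate 2 or 3 or adipose replicate 2 or 3, CTSB at 0.0562 to 0.144 and HEXA at 0.0664 to 0.152, and HEXA also after quantile normalization (0.0606). With the replicate block CTSB was at 0.0889 and HEXA at 0.051. No member passed limma's threshold by either count among HOX paralogs 1 to 8 (4 of 16 at an unadjusted p under 0.05), HOX paralogs 9 to 13 (4 of 15), T and NK lymphocyte (2 of 15) and B lymphocyte markers (2 of 10). The same held for neutrophil (1 of 9), erythroid and platelet (0 of 10), endothelial (2 of 11), inflammatory cytokine and NF-kB target (3 of 14), pluripotency (2 of 11) and immediate early and heat shock genes (2 of 13). Camera also called immediate early genes (adjusted p = 0.0235) and monocyte and macrophage markers (0.0432) without bone marrow replicate 3, and MHC class II (0.037) and trophic factors (0.0184) without bone marrow replicate 2. It called trophic factors with the replicate block (0.0415) and mobilization and homing genes with dim probe sets left out (0.0401). Without adipose replicate 1 it called adipogenic genes (0.0405), trophic factors (0.0348) and mobilization and homing genes (0.0313), the last also without blood-derived replicate 3 (0.0406).

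With all arrays camera called 7 of 27 lists at a preset correlation and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05, and fry called 12. By fry, fibroblast matrix and hypoxia lists (adjusted p = 5.3e-05 each), pericyte and osteogenic (0.0105 each) and chondrogenic and trophic lists (0.0275 each) were lower. So were pan-leukocyte and mobilization (0.0292 each), MHC class II (0.0341) and MSC surface lists (0.0412), while adipogenic (0.0231) and cell cycle lists (0.044) were higher. Of the 50 named genes with a call 35 kept it in all 9 fits that left out 1 array, and the 1857 calls became 849, 926 and 994 without bone marrow replicate 1, 2 or 3 and 1077 without adipose replicate 3. Tissue changed between these groups, and whether horse and processing date did too is not given in the sources used here.

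Some genes set the blood-derived cells apart from both control groups. FGF5, SERPINB2, SERPINB10, SLITRK4 and PCSK1 were higher in blood-derived cells than in either. SERPINB2 was at 9.17 ± 0.55 against 4.73 ± 1.15 in bone marrow and 4.01 ± 0.56 in adipose cells, and SLITRK4 was at 7.11 ± 0.29 against 3.05 ± 0.46 and 3.29 ± 0.24. GMFG, C1R, ITGBL1, EPHX1 and RGCC were lower than in either, with GMFG at 3.94 ± 0.30 against 9.01 ± 0.28 and 9.41 ± 0.20, and ITGBL1 at 4.28 ± 0.62 against 7.72 ± 0.25 and 10.10 ± 0.64. EPHX1 encodes a microsomal epoxide hydrolase and RGCC a regulator of the cell cycle. Altogether 72 probe sets (63 genes) were higher and 52 (43 genes) lower in the blood-derived cells against both groups, and 12 were higher against one group and lower against the other. Independent calls would give 3.74, 4.87 and 8.63 such probe sets, but both comparisons share the blood-derived arrays. In 100 simulations of unchanged groups that share these arrays there were 0, a value that leaves out the real effects. Adjusted calls are rare where nothing differs, so the simulated value sets no baseline for the overlap. Part of the excess over independent calls may come from the shared arrays. The 124 probe sets changed in the same direction against both groups became 42, 44 and 72 without bone marrow replicate 1, 2 or 3, and 70 and 66 without blood-derived replicate 2 or 3. Against bone marrow C1R and EPHX1 lost their calls without any 1 of the 6 arrays compared (0.0535 to 0.0889 and 0.0736 to 0.134), and RGCC without any 1 bone marrow array, blood-derived replicate 2 or 3 or adipose replicate 3 (0.053 to 0.151). The log2 difference of EPHX1 ran from -2.93 to -3.36 without any 1 of the 6 arrays. Against adipose cells C1R lost it without blood-derived replicate 1 or 2 or adipose replicate 1 or 3 (0.0627 to 0.0816), and RGCC without bone marrow replicate 1 or 2, blood-derived replicate 2 or 3 or any 1 adipose array (0.0537 to 0.0877). PCSK1 lost its call against bone marrow without bone marrow replicate 1 (0.0508), SERPINB10 without bone marrow replicate 1 (0.0539) or 2 (0.0595), and SERPINB2 without bone marrow replicate 2 or blood-derived replicate 2 or 3 (0.0523 to 0.0578).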

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

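The glucocorticoid lists were added after the data were seen, and every other alternative was planned. No called list or named gene changed direction in the fits where it was followed, which leave out limma-trend, array weights, 2 groups alone, 1 probe set per gene and the 2-fold criterion. With all 9 arrays, 2286 probe sets differed among the groups, 249 between blood-derived and bone marrow cells, 2116 between blood-derived and adipose cells and 1857 between adipose and bone marrow cells, and 124 differed the same way from both controls. Requiring a 2-fold change, a stricter threshold, gave 1491 for the F test, 1192 for blood-derived against adipose and 1037 for adipose against bone marrow. Leaving out dim probe sets gave 479 for blood-derived against bone marrow and 225 against both controls, array weights gave 744 and 249, 1 probe set per gene 488 and 214, and the mean of a gene's probe sets 499 and 216. The cause was not tested. Fitting 2 groups alone, with fewer arrays, gave 1029 for blood-derived against adipose and 77 against both. Leaving out 1 array, also with fewer arrays, gave 1336 to 2101 for the F test, 86 to 384 for blood-derived against bone marrow, 1176 to 2037 for blood-derived against adipose, 849 to 2012 for adipose against bone marrow and 42 to 172 against both. The replicate block, although the labels give no pairing by number, gave 1745, 263, 1625, 1492 and 107 in the same order. Of the calls of named genes 15 were lost and 2 gained with it. Of the lists, 5, 4 and 7 were called in these pairwise comparisons, against 0, 0 and 0 with an estimated correlation (1, 2 and 3 at an unadjusted p under 0.05), and 1, 9 and 12 by fry. They were 6, 5 and 8 with the replicate block, and 4 to 10, 3 to 7 and 4 to 9 without 1 array, and the cause was not tested. The 143 calls of named genes made 1287 in the 9 fits without 1 array, of which 1030 were kept and 257 lost, and 10 were gained. Quantile normalization and median centring moved the median of all log2 differences by less than 0.1. A pseudocount was not run, since the values were already on the log2 scale. How far dim probe sets lie above background could not be judged from the values used here.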

Other observations

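The tests on the interferon list, the matrix and single-array tests on the cell cycle list, and the choice of the glucocorticoid genes came only after the results were seen. Bone marrow replicate 1 had the highest level of 9 of 18 monocyte and macrophage markers, with FCER1G at 8.67, TYROBP at 8.13 and AIF1, a macrophage marker, at 6.19. It also had the highest level of 7 of 13 immediate early and heat shock genes, a list at 0.86 in this array, 0.66 in bone marrow replicate 2 and -0.35 in bone marrow replicate 3, on a log2 scale centred on each gene's mean. Cell cycle genes were highest in blood-derived replicate 2 for 12 of 24 members and in adipose replicate 2 for the other 12, with list levels of 1.32 and 1.31.

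Of 12 genes known to be induced by glucocorticoids 5 were higher in adipose than in bone marrow cells and 6 lower in blood-derived than in adipose cells. They were chosen after their values had been seen, so these counts are no test of a shared change. FKBP5, a chaperone of the glucocorticoid receptor, was 24.1-fold higher (10.45 ± 0.13 against 5.86 ± 0.10, adjusted p = 3.7e-04), GLUL, glutamine synthetase, 10.5-fold higher (adjusted p = 0.00722), and CRISPLD2 6.49-fold higher (adjusted p = 8.0e-04). MAOA, monoamine oxidase A, was 4.86-fold and ZBTB16, a transcription factor, 3.01-fold higher.

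Glucocorticoid exposure or response of the adipose cultures is a hypothesis from these genes, and 15 measured genes whose values had not been seen were tested for it. Their median was 0.21 in adipose against bone marrow cells (camera p = 0.102, or p = 0.45 with an estimated correlation). In blood-derived against adipose cells it was -0.35 (camera p = 0.0173, or p = 0.284 with an estimated correlation). Over all probe sets 3 members were lower there, FOXO1, CITED2 and PIK3R1. FOXO1 and CITED2 had adipose means above bone marrow, by 2.29 and 1.10 on the log2 scale. PIK3R1 was at 6.12 ± 0.21 in blood-derived, 7.87 ± 0.32 in adipose and 7.84 ± 0.20 in bone marrow cells. This comparison therefore also reflects changes of the blood-derived cells. In adipose against bone marrow cells 2 of the 15 were higher, FOXO1 (4.89-fold, adjusted p = 0.00223) and PDK4 (6.07-fold, adjusted p = 0.044), and ANGPTL4 was at 4.98 ± 1.51 against 7.14 ± 0.18 (adjusted p = 0.0803). The bound set beforehand, a p at or above 0.05 counting against the hypothesis, was wrong, since a p that misses the threshold leaves the size of a difference open. After quantile normalization the median of the genes already seen was 0.71 ± 0.56 (SE over genes). This decides nothing on the submitters' normalization, since the step moved the log2 differences by a median of 0.03. The labels name no such hormone, and a possible separate processing date of the adipose samples cannot be told apart from tissue.

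The lower interferon list of the blood-derived cells depended in its size on bone marrow replicate 3, since its median of -1.80 against bone marrow became -0.61 ± 0.16 (SE over genes that are not independent) without that array, where camera still called the list at the preset correlation (adjusted p = 2.1e-07). Quantile normalization left the median with all arrays at -1.81 ± 0.25 (SE over genes) but moved the log2 differences by a median of only 0.01, so the submitters' normalization stays open. T and NK lymphocyte markers were highest in that array for 8 of 15 members (one-sided exact binomial p = 7.2e-05 against 1 in 9, with genes that are not independent), against 5 of 11 pericyte and smooth muscle, 4 of 13 pan-leukocyte, 2 of 18 macrophage and 0 of 10 B lymphocyte markers, and MHC class II and inflammatory cytokine genes were at list levels of 1.31 and 1.07 there. The excess was therefore not particular to T and NK markers, and lymphocytes left in that culture may be 1 candidate source among others. On each gene's probe set of the highest mean, CD3E was at 5.86, GZMB at 6.87, NKG7 at 7.75 and PTPRC at 4.51 there. PTPRC, of the pan-leukocyte list, thus lay below the median of all values, 4.62. GZMB has further probe sets whose levels are not given here. Levels of single genes in 1 array do not show by themselves whether they were raised. Non-adherent cells had been removed, and how many lymphocytes stayed was not measured. Whether such cells brought or induced interferon transcripts, or that horse had an interferon response of its own, was not tested.

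The higher cell cycle list of the blood-derived cells, with a median of 1.92 against bone marrow, did not rest on 1 array. The lowest median without an array was 1.56 ± 0.20 (SE over genes that are not independent, which leaves out the spread between arrays). Quantile normalization left the median with all arrays at 1.89 ± 0.20 (SE over genes), but moved too little, as for the interferon list, to decide on the submitters' normalization. Dilution of the bone marrow cultures by non-dividing cells of another type would lower the matrix genes there by about as much only if those cells lacked them. Such a fall also assumes equal matrix levels in the undiluted cells of both groups. Neither is known, so the fibroblast matrix difference of -0.19 ± 0.37 (SE over genes) decides nothing on dilution. At the preset correlation camera called the monocyte and macrophage (adjusted p = 0.00111) and pan-leukocyte lists (0.00911) lower in the blood-derived cells. Both were at 0.618 with an estimated correlation, and the lymphocyte and neutrophil lists were not called. The rise over bone marrow was not particular to the treated cells, since adipose cells of untreated horses also had a median of 1.65 against bone marrow. Blood-derived against adipose cells had a median of 0.44 without a call (camera adjusted p = 0.0844). List levels (mean ± SD of 3 arrays) were -1.16 ± 0.15 in bone marrow, 0.79 ± 0.46 in blood-derived and 0.36 ± 0.88 in adipose cells. Dilution stays open, and tissue, treatment and horse stay open and untested. The adjusted p = 0.618 with an estimated correlation leaves the cell cycle list's call against bone marrow dependent on the preset value.

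Other splits of the arrays were counted for each comparison. Of 100 splits of the 9 arrays, drawn from 280 with the real one included, 1, the real one, gave 2286 probe sets by the F test. The highest other count was 785. A share of 1 in 100 is the lowest that 100 splits can give. If the arrays can be exchanged, it makes chance unlikely for that count but does not exclude it. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Among these 1, the real one, reached the count of 249 for blood-derived against bone marrow (highest other 1), 1 reached 2116 for blood-derived against adipose (highest other 3) and 1 reached 1857 for adipose against bone marrow (highest other 0).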
